A study of Bos taurus with 6 samples.

How the data were processed

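Gene expression was measured on 6 Affymetrix bovine arrays, 3 from fetal ovarian cortical pieces cultured for 2 days in control medium and 3 from pieces cultured for 2 days with insulin. Each array was hybridised with biotin-labelled complementary RNA made from total RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

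The deposited value table held 1 linear signal intensity per probe set and array, which the authors had already scaled. GCOS, the Affymetrix array software, is named in the submitters' processing notes, and its version, algorithm settings and scaling target are not given in the sources used here. Array upper quartiles lay between 621 and 633 and medians between 196 and 212. The table covered 24128 probe sets, of which 112 were Affymetrix control probe sets. For arrays, the precision is limited by their number, here 3 per group.

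The authors also deposited a table of 158 probe sets with their own comparison of insulin with control. Its log2 column holds the authors' log2 ratio of insulin over control, per the file headers, and its fold column is the same ratio on the linear scale, deposited by the authors. The authors' deposited p-value column stayed below 0.001 in every row, with a largest value of 0.000998. The authors' deposited t column, a score per probe set, gave those p-values with 4 degrees of freedom to within 0.412%. The test and the filter behind that table are not given in the sources used here. Of its per-array columns, 9 were not used, because 3 carried day 0 names, 4 showed a group but no sample and 2 matched no sample or group.

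Among the sources used here, only the authors' deposited table pairs probe sets with names. It gave a symbol for 105 rows and none for 53. A RefSeq table of assembly ARS-UCD2.0, used for names only, matched 77 of the 105, with 33 by symbol, 35 by gene number and 9 by synonym, and 28 stayed unmatched. For 24 rows the gene was read from the row's title after the data were examined, among them CXCL14, SAT1, HSD17B11, SQLE, EBP, CENPA, UBE2C and the second PSAT1 probe set. In all 101 rows had a current gene name or one read from the title, 0.658% of the probe sets on the array being covered by that table. No coordinates are given, because no genome build was named with the values.

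Signals were analysed as log2(signal + 16), so a log2 difference understates the change of dim probe sets. Control probe sets and the 40% of probe sets with the lowest mean over all arrays were left out, which placed the filter at a mean signal of 122 and left 14410 probe sets. Insulin was compared with control with limma (3.58.1, in R 4.3.3; lmFit and eBayes), without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard errors given are those of limma, and the signals are means ± SD over 3 arrays. The labels do not say whether replicates came from separate fetuses or cultures, so p-values measure the spread between these samples, which may be technical. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

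Replicate numbers in the titles were checked for pairing before the calls of the fits were compared. Deviations from the group means correlated between same-numbered control and insulin arrays at 0.56, 0.31 and 0.42 for numbers 1, 2 and 3. Between arrays of different number these correlations ran from -0.41 to 0.13. The 3 deviations of a probe set within a group sum to 0, so values for different numbers partly follow from those for the same number. Any pairing is thus read from the data and not from the labels, and 3 pairs are too few to settle it. A fit with the replicate number as a block is given beside the counts it moves. Replicates of a group correlated at 0.962 to 0.972 over log2 signals, with at most 1 identical value, so each was counted as its own sample.

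Named genes followed a rule fixed before the data were examined, except for list members. It took the 10 higher and 10 lower named probe sets with the largest change past the threshold. It also took the 5 largest folds in each direction in the authors' deposited table. List members were to be chosen by the planned gene set tests. As those were not run, every named row of the lists was taken, some through names read from titles. The rule further held a short set of genes of follicle biology where named, such as KIT, GDF9, AMH and FOXL2. The authors' table names no gene of that set, so it was not analysed here. The 28 gene lists were also fixed beforehand. The planned gene set tests over all genes (camera and fry) and the planned choices among probe sets of a gene were not run, since they need a name for every probe set. In their place, added after the data were examined, the direction of each list's rows was set against the other rows of the authors' table with a two-sided Fisher's exact test, for lists with at least 3 rows.

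The fit was tested on simulated data for the 14410 probe sets with 200 of them changed. It called 0 of the 200 at a change of 1.5-fold, 118 at 2-fold and 171 at 3-fold, with 0, 5 and 11 unchanged probe sets called. With no change simulated it called 0. The simulated noise was independent for each probe set and array, without the deviations that same-numbered real arrays share. These counts may therefore not hold for the real arrays. Alternatives covered the pseudocount, the filter, the scaling between arrays, the block, the variance model, array weights, an ordinary t statistic, and leaving out each array or each replicate pair.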

Results

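Transcript levels were measured in cortical pieces of fetal bovine ovaries collected at slaughter. Pieces were kept for 2 days either in control medium (TS+, with transferrin, selenous acid, albumin and linoleic acid) or in medium with insulin (ITS+), which the submitters describe as a stimulus of follicle activation. Per the series description, control pieces were enriched for primordial follicles, the resting stage, and insulin pieces for primary follicles, the first growing stage. Each group had 3 arrays, numbered 1 to 3. Median signals of the 6 arrays lay between 196 and 212.

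The comparison asked how the transcriptome of cultured cortex differed between the insulin and control media. With insulin, the named genes of cholesterol synthesis were higher, as were SCD and FASN of fatty acid synthesis, PHGDH and PSAT1 of serine synthesis and RRM2 and CDC20 of the cell cycle, and CXCL14, a chemokine, and SAT1, an enzyme of polyamine breakdown, were lower. Stearoyl-CoA desaturase (SCD), which makes monounsaturated fatty acids, had the largest rise among named genes, from 821 ± 43.7 to 3434 ± 266 (SD, n = 3 each), a log2 difference of 2.04 with an SE of 0.12 and a limma adjusted p of 0.00151. CXCL14 had the largest fall among named genes, from 597 ± 24.5 to 122 ± 15.4 (SD, n = 3 each), a log2 difference of -2.16 with an SE of 0.13 and a limma adjusted p of 0.00151.

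All named rows of the cholesterol synthesis list rose. The authors' deposited table named 10 probe sets of 9 of its 24 genes. Of these probe sets, 10 of 10 passed the test, with a median of 1.93-fold and a range of 1.67 to 2.30-fold. HMGCS1, which makes the HMG-CoA used by the pathway, rose from 3925 ± 282 to 7922 ± 172 (SD, n = 3 each), by 1.01 on the log2 scale. INSIG1, a sterol-regulated protein of the endoplasmic reticulum that restrains the pathway, rose by 1.20, and SQLE, the squalene epoxidase, by 1.09. A probe set titled isopentenyl-diphosphate isomerase rose by 1.06, EBP by 0.96, ACAT2 by 0.94, CYP51A1 by 0.80 and MVK by 0.75. The pair of FDFT1 probe sets rose by 0.74 and 0.75. The largest limma adjusted p among the 10 was 0.0270. Of the 10, 0 passed without control replicate 3, 1 without insulin replicate 1 or insulin replicate 2, 2 without insulin replicate 3, 3 without control replicate 2, 0 with no filter and 1 with an ordinary t statistic. The excess of higher rows over the rest of the authors' table had a Fisher's exact p of 0.00523, 0.0157 after adjustment over 3 lists. With names from symbols alone, 7 of 7 rows, of 6 genes, were higher, with an exact p of 0.0198, 0.0396 adjusted over 2 lists. Both tests count rows as independent, though FDFT1 enters each with 2 probe sets and genes of a shared pathway may change together. No test with 1 row per gene was run, so these p-values may be too small.

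From the fatty acid synthesis list of 19 genes, only SCD and FASN, the fatty acid synthase, were named, and both rose. FASN went from 1501 ± 122 to 2947 ± 67.0 (SD, n = 3 each), by 0.97 on the log2 scale. Another probe set with the same cluster number as FASN, which carries no name here, had a log2 difference of 0.06 and a limma adjusted p of 0.897. From the list of 23 amino acid and unfolded protein response genes, 3 of 3 named rows rose. All belong to PHGDH and PSAT1, consecutive enzymes of serine synthesis, and the list's other genes had no named row. PHGDH rose from 472 ± 101 to 1771 ± 76.1 (SD, n = 3 each), by 1.89 with an SE of 0.17 and a limma adjusted p of 0.0118. PSAT1 rose from 1454 ± 200 to 3985 ± 340 (SD, n = 3 each), by 1.45, and a probe set named PSAT1 from its title rose by 1.22. Fisher's exact test of the direction of the 3 rows against the rest of the authors' table did not pass (p = 0.260, adjusted p = 0.260 over 3 lists). Of the 3 rows, 1 passed without control replicate 3 and 0 with no filter or an ordinary t statistic. FASN did not pass with no filter, with an ordinary t statistic, or when any single array other than control replicate 1 was left out.

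From the cell cycle and mitosis list of 36 genes, 4 of 4 named genes rose, with a median of 2.25-fold. The list's other genes had no named row and were not examined. RRM2, a subunit of the enzyme that makes deoxynucleotides, rose by 1.44 with an SE of 0.16 and a limma adjusted p of 0.0118. UBE2C and CDC20, which act with the anaphase-promoting complex, rose by 1.34 and 1.00, and the mitotic kinase AURKB by 0.91. Of the 4, 0 passed without control replicate 3, 1 without insulin replicate 2, 2 without insulin replicate 1 or control replicate 2, and 0 with no filter or an ordinary t statistic. Fisher's exact test of their direction against the rest of the authors' table did not pass (p = 0.135, adjusted p = 0.202). Outside the lists, SPAG5 and CKAP2, both proteins of the mitotic spindle, rose by 1.34 and 1.32, CENPA, the histone of centromeres, by 1.31, and KIAA0101, a partner of the replication clamp PCNA, by 1.28. Another probe set with the same cluster number as CKAP2 had a log2 difference of 0.58 and a limma adjusted p of 0.134. SLC52A3, a riboflavin transporter, rose from 199 ± 8.96 to 599 ± 47.5 (SD, n = 3 each), by 1.51 with an SE of 0.12 and a limma adjusted p of 0.00887.

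Among genes that fell with insulin, SAT1 went from 10373 ± 269 to 4320 ± 590 (SD, n = 3 each), a log2 difference of -1.27 with an SE of 0.14 and a limma adjusted p of 0.0118. HSD17B11, a dehydrogenase acting on steroids and lipids, had a log2 difference of -1.21, and MGC126930, titled as similar to a calcium channel gamma subunit, one of -1.22. BCL6, a transcriptional repressor and the only named member of the FOXO target list, fell from 2468 ± 263 to 1200 ± 81.7 (SD, n = 3 each), by 1.03 on the log2 scale. Further falls past the threshold were those of C21H14orf132 (-0.99), MTURN (-0.95) and F11R, a junctional adhesion molecule (-0.91). Of the hypoxia response list, MXI1, an antagonist of MYC, fell by 0.91, while KDM3A, a histone demethylase, had a log2 difference of -0.34 and a limma adjusted p of 0.165. The ribosomal protein list was represented by RPL5 alone. One of its 2 named probe sets fell by 1.16. The other had a log2 difference of -0.46 and a limma adjusted p of 0.0880, so the 2 disagree in size. Unnamed probe sets with the same cluster numbers had log2 differences of -0.81 and -0.50. Their limma adjusted p were 0.0865 and 0.124, so neither passed. CCN1, the only named member of the YAP and Hippo target list, had a log2 difference of -0.43 and a limma adjusted p of 0.109. With no filter on dim probe sets no fall in this paragraph passed, as only SCD and CXCL14 did. Without control replicate 3, only 1 lower probe set passed among all those tested.

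The authors' table was chosen on these same arrays, so the direction of any list within it is not independent evidence. Adjusted over the list alone, all named rows of the 8 lists passed, KDM3A and CCN1 included, but rows chosen at the authors' p below 0.001 could hardly do otherwise, so that count adds no evidence. Of the 28 fixed lists, 20 had no named row and were not analysed here. These were the oocyte, germ cell, granulosa, theca, insulin receptor and PI3K, IGF, glycolysis, extracellular matrix, protease, TGF-beta and BMP, immediate early, apoptosis, inflammation and interferon lists, and the markers of endothelium, smooth muscle, leukocytes, red blood cells, surface epithelium and stroma.

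**Figure D1:**
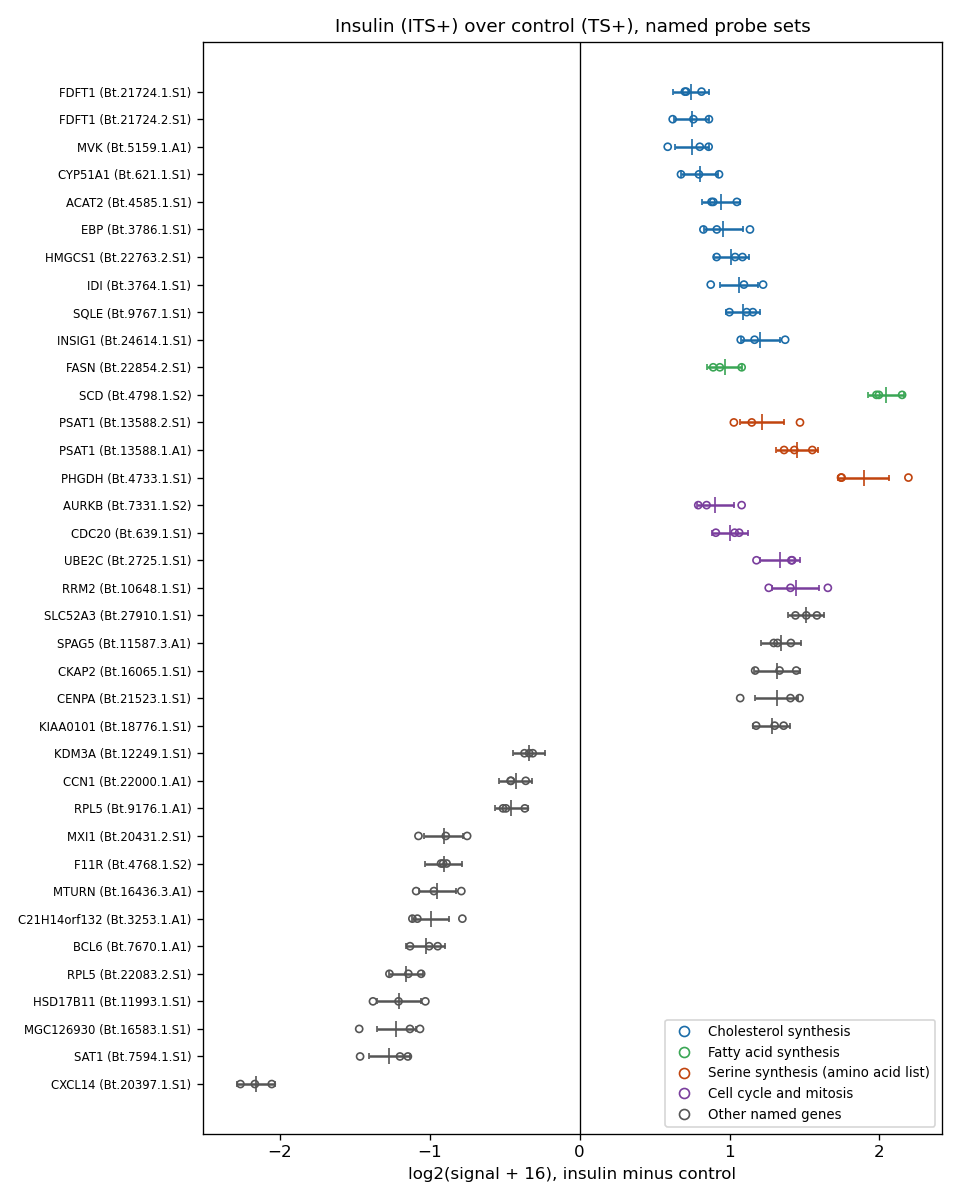
Log2(signal + 16), insulin minus control, for the named probe sets, grouped by gene list. Open circles are the 3 same-numbered pairs, the tick is the mean and the bar is 1 limma SE on each side. SCD sits highest at 2.04 and CXCL14 lowest at -2.16, and the 3 pairs of each probe set lie on one side of 0.

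Over all probe sets tested, 326 of 14410 passed the limma threshold of 0.05, 170 higher and 156 lower with insulin. Their median absolute log2 difference was 0.95, and 137 of them changed at least 2-fold. With the replicate number as a block, 916 passed, 447 higher and 469 lower, and all 326 were among them. Of the 326, 231 are outside the authors' deposited table and so have no name here. The largest rise among these was that of Bt.227.2.A1_a_at, from 1438 ± 522 to 8814 ± 1627 (SD, n = 3 each), by 2.65 on the log2 scale, and the next rose by 2.46. The largest falls among these had log2 differences of -2.38 and -2.08. The count was 3 without control replicate 3, 30 without insulin replicate 1, 40 without insulin replicate 2, 49 without control replicate 2 and 59 without insulin replicate 3. With no filter on dim probe sets it was 2, SCD and CXCL14.

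**Figure D2:**
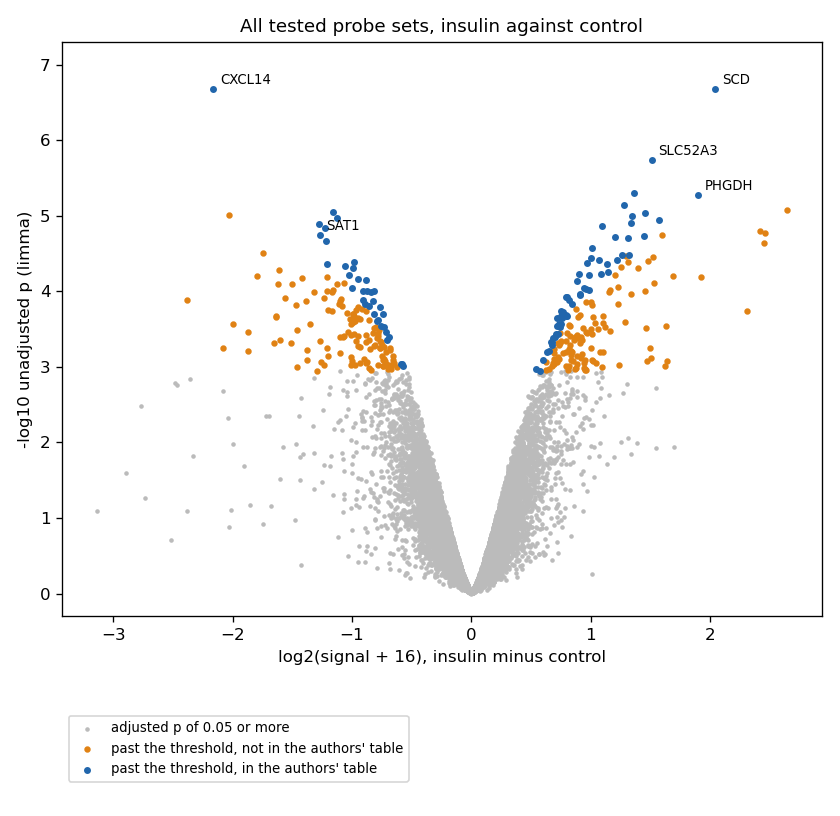
Log2(signal + 16), insulin minus control, against -log10 of the unadjusted limma p for the 14410 probe sets tested. Grey points did not pass, orange points passed and are not in the authors' deposited table, and blue points passed and are in the authors' deposited table. SCD and CXCL14 stand at the top of either side, and the 170 higher and 156 lower probe sets spread to both sides.

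The authors' deposited table was then set against the same signals. It listed 90 probe sets as higher and 68 as lower with insulin, and among rows with a symbol its largest rises were SCD (2.02), PHGDH (1.86), SLC52A3 (1.45), PSAT1 (1.44) and RRM2 (1.42) on its own log2 scale. Its largest falls among rows with a symbol were CXCL14 (-2.04), SAT1 (-1.27), HSD17B11 (-1.20), MGC126930 (-1.19) and RPL5 (-1.14). Over the 158 rows of the authors' deposited table, its log2 ratios and those computed here correlated across probe sets at 0.9996, with 158 of 158 of one sign and a largest difference of 0.16. Probe sets are not independent replicates. Of the 152 rows that were tested, 95 passed the limma threshold, 59 higher and 36 lower, and 63 of the 95 have a current gene name or one read from the title. With the replicate number as a block, 106 passed. Without the block the other 57 rows did not pass, and 6 rows of the authors' deposited table lay below the filter. These counts use an adjusted limma p, unlike the authors' p-values, which lie under 0.001 and match a t statistic with 4 degrees of freedom. An ordinary t test on these log2 signals gave 163 probe sets with an unadjusted p under 0.001. Of the 163, 152 were in the authors' table, whose rows had a largest such p of 0.00126. The 95 fell to 12 with an ordinary t statistic after adjustment and to 2 with no filter. With no filter and a trended robust variance, 100 rows passed.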

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

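The tests of other splits of the arrays and of RNA integrity were chosen after the counts and directions had been seen, and the choice of 4 control transcripts after their ratios had been seen.

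The array carries control probe sets that the comparison left out. Those for GST, a glutathione S-transferase, had every insulin array above every control array, with ratios of insulin over control of 1.44 at the 3-prime end, 1.33 in the middle and 1.57 at the 5-prime end. The 3-prime probe set for glyceraldehyde phosphate dehydrogenase did so at a ratio of 1.11. In 1 other control probe set every insulin array lay below every control array, at a ratio of 0.883, and the remaining ones of the 18 bright bovine control probe sets overlapped. For each of the 5 the exact permutation p was 0.1, the smallest that 3 against 3 allows.

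The 15 named probe sets of cholesterol, fatty acid and serine synthesis all rose, with a median log2 difference of 1.01, though of their lists cholesterol synthesis passed its test of direction, the amino acid list did not, and fatty acid synthesis had too few rows for one. Quantile normalization left that median at 0.97, against a remaining difference in array scaling. The arrays had already been scaled to similar levels, so the normalization had little to change. The log2 ratio of 3-prime to 5-prime signal of 6 control transcripts differed between the groups by a mean of -0.00943 (SE 0.0509). These SE measure the spread between transcripts, not between arrays. Single transcripts ranged from -0.13 (GST) to 0.22 (ef1a), so opposite shifts partly cancelled. The mean was -0.0615 (SE 0.0322) over the 4 left without actin, whose 5-prime probe set was dim, and ef1a, whose 5-prime probe set was the brightest on some arrays. Shifts of this size argue against RNA integrity as the whole cause. Other probe sets with the same cluster numbers, which the authors' table does not list, had a median of 1.29 in 3 probe sets, where 95% of random draws lay between -0.38 and 0.36, which argues against a fault of single probe sets for HMGCS1 and PSAT1 (log2 differences of 1.69 and 1.29) and leaves it open for FASN (0.06) and for genes with no further probe set. A response to insulin, directly or through the follicle stages the media enrich, may be the source, as a hypothesis found and examined on the same arrays; a change in the mix of cells was not tested, since no cell type marker has a name here.

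The 4 named genes of the cell cycle list rose too, though the list did not pass its test of direction. Their median log2 difference was 1.17, and quantile normalization left it at 1.18. As above, arrays already scaled to similar levels left the normalization little to change, so this argues only against a remaining difference in scaling. A fault of single probe sets stays open, because only 1 further probe set shares a cluster number, that of AURKB. It had a log2 difference of 0.63 (SE 0.13, limma adjusted p 0.0604), where 95% of random draws lay between -0.65 and 0.59, so it exceeded that range by less than its SE. More dividing cells with insulin is a candidate explanation that these arrays cannot tell from higher transcript levels per cell.

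Over all rows of the authors' table, 42 further probe sets share a cluster number with a row, and 40 of them moved in that row's direction, 9 past the threshold. Their median in that direction was 0.47, where 95% of random draws lay between -0.09 and 0.09, which argues against faults of single probe sets for the table as a whole.

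The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 326 probe sets past the threshold and the highest other 23; for higher probe sets these counts were 170 and 21, and for lower ones 156 and 21. In each case 1 of the 10 splits reached the real count. That highest other split set both replicate 1 arrays and insulin replicate 2 against the rest. Of the 4 splits that part all 3 pairs, the 3 others gave 0 in limma with and without the block, against 916 and 326. They exchange the labels within 1 pair. Every split but the real one mixes insulin and control arrays on a side. A real difference would widen the spread there and lower the count, so these counts do not measure calls without an effect.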

How the results depend on the processing

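The fit with the block and quantile normalization, the unfiltered fit with a trend, the pair-wise omissions with a block and the counts over the authors' rows and the lists were chosen after seeing the data. All changes kept their sign under every setting run for the named genes.

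The count of 326 (170 higher, 156 lower) was within 1.5 times of itself under a pseudocount of 1 (309) or 64 (376), a filter at 60% (402), quantile normalization (322), median centring (329) and no filter with a trended robust variance (423). It was 2 (1 higher, 1 lower) with no filter, 12 (7 and 5) with an ordinary t statistic, 542 (286 and 256) with a trended robust variance, 605 (311 and 294) with array weights, 916 (447 and 469) with the replicate block and 944 (470 and 474) with block and quantile normalization. The cause of these moves was not tested.

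Leaving out an array or a replicate pair gave 0 to 242 probe sets, 0 to 121 higher and 0 to 121 lower. Single arrays gave 242 without control 1, 49 without control 2, 3 without control 3, and 30, 40 and 59 without insulin 1, 2 and 3. Without a pair, limma called 7 (pair 1), 0 (pair 2) and 0 (pair 3), where 1402 and 1491 probe sets had an unadjusted p under 0.05 without pair 2 and pair 3. Fewer samples were fitted in all of these. With the replicate block kept, the counts were 150 (66 higher, 84 lower) without pair 1, 394 without pair 2 and 313 without pair 3.

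Of the authors' rows, 95 passed, against 2 with no filter, 12 with an ordinary t statistic, 0 to 70 with an array or pair left out, and 27 and 57 with the block and without pair 1 or pair 3. Of the 10 cholesterol rows, 0 passed with no filter, 1 with an ordinary t statistic, 0 to 7 with an array or pair left out, and 3 and 6 with the block and without pair 1 or pair 3. Of the 2 fatty acid rows these counts were 1, 1 and 0 to 2, and 1 with the block and without pair 1. Of the 4 cell cycle rows they were 0, 0 and 0 to 4, and 2 with the block and without pair 1. Of the 3 amino acid rows they were 0, 0 and 0 to 3.

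The replicate block changed no call among the 37 probe sets named by the rule or as list members, while CDK4 and SLC38A2, named below, gained one, as did further rows of the authors' table. Of the 37, 32 lost their call with no filter, and 29 did with an ordinary t statistic, where KDM3A gained one. With no filter but a trended robust variance, 36 of the 37 were called or not called as before and 1 gained a call. Leaving out control 1, 2 or 3 ended 3, 14 or 31 of these calls, leaving out insulin 1, 2 or 3 ended 21, 21 or 17, and leaving out pair 1, 2 or 3 without the block ended 32, 34 or 34. With the replicate block kept, leaving out pair 1, 2 or 3 ended 15, 1 or 4. The other named RPL5 probe set, not called above, passed with a filter at 60%, with a trended robust variance (with and without the filter) and with block and quantile normalization. A filter at 60% took CXCL14, CKAP2, MTURN, AURKB and CCN1 out of the test. Camera with an estimated correlation, fry, and the mean or the dimmest probe set per gene were not run. Low signal limits the rest, since the 40% of probe sets with the lowest mean were left out untested.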

Other observations

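The genes of this part were chosen after their values were seen, and the tests of annotation terms were added then.

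Several genes of the authors' table outside the fixed lists rose with insulin in limma; they form no tested group. ESPL1, the protease that releases sister chromatids, rose by 1.15 on the log2 scale, LMNB1, lamin B1 of the nuclear envelope, by 1.08, and DTYMK, which makes thymidine diphosphate, by 0.90. EZH2, a histone methyltransferase, rose by 0.79, SPDL1, a kinetochore protein, by 0.77, RRM1, the partner of RRM2, by 0.60, and FEN1, a flap endonuclease, by 0.57 with an adjusted p of 0.0499. CDK4 had a log2 difference of 0.57 and a limma adjusted p of 0.0522, which did not pass, and 0.0382 with the replicate block. SERPINA5, a serine protease inhibitor, rose from 5076 ± 433 to 9125 ± 514 (SD, n = 3 each), and LGALS1, galectin 1, from 7988 ± 365 to 13162 ± 398 (SD, n = 3 each).

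Of single genes with mitochondrial products, ATP5MC1, a subunit of ATP synthase, rose by 0.82, BCKDHB, of branched-chain amino acid breakdown, by 0.79, and NDUFA11, of complex I, by 0.67. Another probe set with the same cluster number as BCKDHB had a log2 difference of 0.16 and a limma adjusted p of 0.568. UQCRFS1 of complex III and COX8A of complex IV had log2 differences of 0.35 and 0.18 and limma adjusted p of 0.165 and 0.445. Of the table's 8 rows annotated to the mitochondrion, 7 were higher (Fisher's exact p = 0.108, adjusted p = 0.433 over 12 terms), and of 12 annotated to oxidoreductase activity, 11 were higher (exact p = 0.0478, adjusted p = 0.433), so neither passed. Lower with insulin were CD55, a complement inhibitor (-0.89), HBP1, a transcriptional repressor (-0.88), KLHL24 (-0.86), GLUL, the glutamine synthetase (-0.77), and FZD1, a Wnt receptor (-0.74), all past the threshold. SLC38A2, a transporter of neutral amino acids, had a log2 difference of -0.55 and a limma adjusted p of 0.0585, and 0.0328 with the block.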
